A study of Mus musculus and Homo sapiens with 9 samples.

How the data were processed

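ChIP-seq was performed on B16 mouse melanoma cells and on the human lung cancer line H1299. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min and chromatin was sheared to about 300 bp. The samples fell into 9 groups of 1 library each, by antibody, genotype and treatment in the labels. Peak lists of 2 groups were analysed, the HA antibody and the p53 antibody in B16 cells with HA-tagged Tdg. The other 7 samples, among them H1299 cells with tagged TDG given DMSO or the compound C-271, and the CUT&Tag profiles named in the series design were not analysed here.

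Trim Galore, Bowtie2, Picard, deepTools, MACS2 and ChIPseeker and the genome build mm10 are named per the submitters' processing notes, without versions, roles or order. The authors deposited each list in the narrowPeak layout of MACS2. The deposited fold enrichment was taken as the ratio of the summit to the caller's local background after the same small constant is added to both. It is therefore lower than the plain ratio of reads. The authors' −log10 p and −log10 q values belong to the summit, and the deposited score equalled 10 times the −log10 q, cut to a whole number, for 3410 of 3410 TDG peaks and 126 of 126 p53 peaks. The other deposited columns are positions in bases. The control library, the calling threshold and the versions are not given in the sources used here. The lowest −log10 q was 3.02 in the TDG list and 3.74 in the p53 list. The fold enrichments were used only within their own list, to describe, rank, filter and test peaks and to recover the local background.

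Library totals are not part of the lists. The local background was recovered for each peak by solving the MACS2 formulas for fold enrichment and Poisson p together. The most frequent value, taken as the genome-wide background, was 2.558 reads for TDG and 2.028 for p53. The reads had been scaled by 0.924 and 0.7924. With these scales the summits came out as whole reads, within 0.05, for 100% of TDG peaks and 99.21% of p53 peaks. Fractional local backgrounds below 10 reads were whole reads in 10 kb at fragment lengths of 261 bases for 99.85% of 680 TDG values and 197 bases for all 15 p53 values, within 0.001 reads. Dividing the genome-wide background by this length, a step added after the data had been seen, gave the control reads per kb. A local background of at least 10 reads, a limit set after the lists had been seen, marked 15 TDG and 23 p53 peaks as regions of high background.

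Genes came from a RefSeq table of GRCm38.p6, whose coordinates are those of mm10, with 21887 protein-coding genes on placed chromosomes. The table gives no strand and no genome sequence was used. The planned promoter class was therefore replaced by summits within 1 kb of either end of a protein-coding gene. The planned tests of CpG content, of p53 sites and of other motifs, and the comparison among CpG-rich promoters, were not run. A p53 peak was assigned to genes that held its summit and to the gene with the nearest end.

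The tests, gene lists, alternatives and rule for named genes were chosen before the data were examined, except where stated. The rule named the Tdg and Trp53 loci, the 15 peaks of each list with the highest fold enrichment, the p53 peaks overlapping a TDG peak, and for each gene list up to 4 members with a peak by fold enrichment, or 10 for p53 targets. The names gave 55 distinct protein-coding genes from 58 p53 target names, 39 from 43 innate immune names, 21 from 35 histone names and 21 from 22 CREB target names. The histone and innate immune names included older and newer symbols of the same gene, which were counted once, so the shortfall there overstates the genes missed. The other 9 lists matched in full. The TDG peaks at Cdkn1a other than the shared one, the further p53 targets with a p53 peak and the regions of high background were named after their values were seen. So were the p53 targets with peaks of both kinds, and Lmna, Maml1, Myc and Nfe2l2.

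Shares at gene ends were compared with 1000 shuffles, overlaps with 10000 shuffles of the p53 peaks, and medians with 100000 permutations. Shuffled peaks kept their chromosome and width and fell between the first and last annotated gene. On unplaced sequence, where the genes used gave no such limits, they fell between the first base and the end of the last peak. Assembly gaps could not be avoided. Gene lists were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 13 lists. Intervals of shares are exact binomial 95% intervals and cover counting error only. Neighbouring peaks and genes are not independent replicates. The alternatives set beforehand were a 3 kb window, a −log10 q of at least 5, peaks at or above the median fold enrichment, ends of all annotated genes, other definitions of overlap, −log10 q as the strength, a p53 assignment by gene ends within 10 kb, and the lists without unplaced sequence. Leaving out regions of high background, drawing list genes from the same chromosomes, joining neighbouring p53 peaks into regions and keeping windows with at least 1 TDG peak were added after the data had been seen. An added alternative without the genes of overlapping peaks removed genes by the outcome and was given as a share without a test.

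The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data first. For the local background, 100% of 500 simulated peaks were recovered within 1 percent. For the overlap test, 0 of 50 unrelated lists passed the 0.05 threshold and all 20 placed overlaps were found. The unrelated peaks were placed evenly along each chromosome, as in the shuffles, so unrelated peaks that gather at gene ends were not simulated. For the gene lists, 20 of 500 random lists passed it.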

Results

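The series used chromatin immunoprecipitation and sequencing (ChIP-seq) to locate thymine DNA glycosylase (TDG), a base excision repair enzyme that removes thymine and oxidised methylcytosine from DNA, and the transcription factor p53. Of its 9 samples, 6 came from B16 cells, a mouse melanoma line, and 3 from H1299, a human lung cancer line. Peak lists were analysed for 2 B16 samples, both from cells in which the Tdg gene carries an HA tag. The HA antibody was used to locate tagged TDG in 1 library and the p53 antibody to locate p53 in the other. Peaks of the HA list are called TDG peaks here, but whether they depend on the tag was not tested. Likewise, whether the p53 peaks depend on p53 was not tested. The other 7 samples, which include the input, the IgG sample, the HA antibody in untagged cells and the p53 antibody in Trp53 knockout cells, were not analysed here. Each list therefore stood for 1 library with no replicate, every fold enrichment is the authors' value for that peak, and each p describes positions within these libraries rather than the spread between cultures.

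The first question was where TDG and p53 lay along the genome. TDG was called at 3410 peaks with a median fold enrichment of 5.74 and quartiles of 4.95 and 6.77. The p53 list was shorter, with 126 peaks, and its median fold enrichment was 13.5 with quartiles of 7.96 and 22.4. The median TDG peak was 420 bases wide and the median p53 peak 306.5 bases. The lists carried no library totals. The recovered control reads were 9.80 per kb for TDG and 10.3 for p53, and the reads had been scaled by 0.924 and 0.7924. If that scaling brought each library down to the depth of its control, the p53 library held more reads per kb than the TDG library. The reads recovered at the summits had a median of 24 for TDG and 77.5 for p53.

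The tagged Tdg gene itself held the TDG peak with the highest fold enrichment. This peak (mm10, chromosome 10, 82629067 to 82630949) reached 28.9-fold with a −log10 q of 132 and 128 reads at the summit. The summit lay 41 bases from the lower end of Tdg (82629814 to 82650799). The next highest TDG peak, at the lower end of Dop1b, reached 14.6-fold. No p53 peak lay within 10 kb of Tdg, and neither list had a peak within 10 kb of Trp53, the gene for p53 (chromosome 11, 69580348 to 69591873). The nearest TDG summit to Trp53 was 40970 bases away.

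After Tdg and Dop1b, the 15 highest TDG peaks lay at Tsga10 (12.7-fold), Avl9 (12.7-fold), Cyp46a1 (12.5-fold), Map3k14 (12.5-fold), Wnt7b (12.2-fold), Setd3 (12.2-fold), B3gntl1 (12.0-fold), Usp5 (11.9-fold), P4hb (11.7-fold), Rmnd5a (11.6-fold), Skap2 (11.6-fold), Pdcl3 (11.4-fold) and Mier3 (11.4-fold). All but 3 of the 15 summits lay within 1 kb of an end of the named protein-coding gene. The exceptions were the summit in the body of Tsga10, 1274 bases from its upper end, the summit 6973 bases from Mier3, and the summit 52842 bases from Wnt7b, which lay in the noncoding gene D130051D11Rik. Map3k14 encodes the kinase NIK of the noncanonical NF-kappaB pathway, and Cyp46a1 encodes cholesterol 24-hydroxylase.

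TDG peaks clustered at gene ends. Of the 3410 TDG summits, 2290 (67.2%, exact 95% interval 65.6 to 68.7%) lay within 1 kb of an end of a protein-coding gene. Another 704 (20.6%) lay elsewhere in the body of a protein-coding gene and 405 (11.9%) lay between protein-coding genes, where noncoding genes were not counted. The remaining 11 were on unplaced sequence. Shuffled peaks of the same widths on the same chromosomes reached 3.24% at gene ends, so the observed share was 20.7 times the shuffled one (two-sided permutation p = 0.002, the smallest that 1000 shuffles can give). The ratio was 8.71 with a 3 kb window and 11.1 with the ends of all annotated genes, where the shuffled share was also higher. In all, 2689 of 21887 protein-coding genes (12.29%) had a TDG peak at an end, and only 41 of them had one at both ends. Of the TDG peaks, 448 lay within 1 kb of the ends of 2 or more protein-coding genes. Each of those counted for every such gene, here and in the gene lists. The annotation used gave no strand, so starts and stops of genes could not be separated: 1365 genes had the peak at the lower-coordinate end only and 1283 at the upper-coordinate end only.

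The p53 peaks lay at gene ends less densely than this. Ends of protein-coding genes held 26 of 126 p53 summits (20.6%, exact 95% interval 13.9 to 28.8%) and their bodies 39 (31.0%). Sequence between protein-coding genes held 53 (42.1%), some of them in noncoding genes, and unplaced sequence held 8. The share at gene ends was 6.39 times the shuffled share of 3.23% (two-sided permutation p = 0.002, the smallest that 1000 shuffles can give), and 3.73 times with the 3 kb window. The median distance from the summit to the nearest gene end was 235 bases for TDG and 8990 bases for p53, against 45444 bases for random positions. The intervals of the TDG and p53 shares did not overlap.

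**Figure D1:**
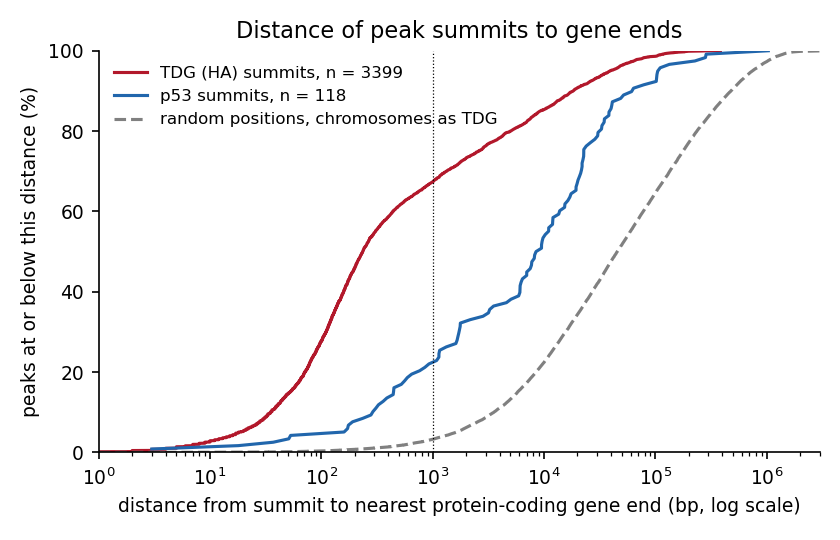
Cumulative share of peaks (vertical axis, percent) by the distance from summit to nearest protein-coding gene end (horizontal axis, bases, log scale) for 3399 TDG peaks, 118 p53 peaks and random positions on the same chromosomes. The dotted line marks 1 kb, below which the TDG curve lies far above the p53 curve, and both lie above random positions.

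Peaks at gene ends were also slightly stronger for TDG. The 2290 gene-end peaks had a median fold enrichment of 5.99 and the other 1120 TDG peaks had a median of 5.49. The difference of 0.508 was small beside the quartiles of either class, 5.14 to 6.94 and 4.87 to 6.51 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give).

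The density of TDG peaks varied between chromosomes. Chromosome 6 had 38.5 TDG peaks per 100 protein-coding genes (exact Poisson 95% interval 35.0 to 42.3), followed by chromosome 15 with 33.1, chromosome 12 with 32.4 and chromosome 16 with 27.8. Chromosome 8 had 6.14, chromosome 18 had 4.70, chromosome 14 had 2.47 (interval 1.53 to 3.77) and the X chromosome 0.207. These intervals cover counting error only. No p53 peak lay on chromosomes 14, 18, X or Y.

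**Figure D2:**
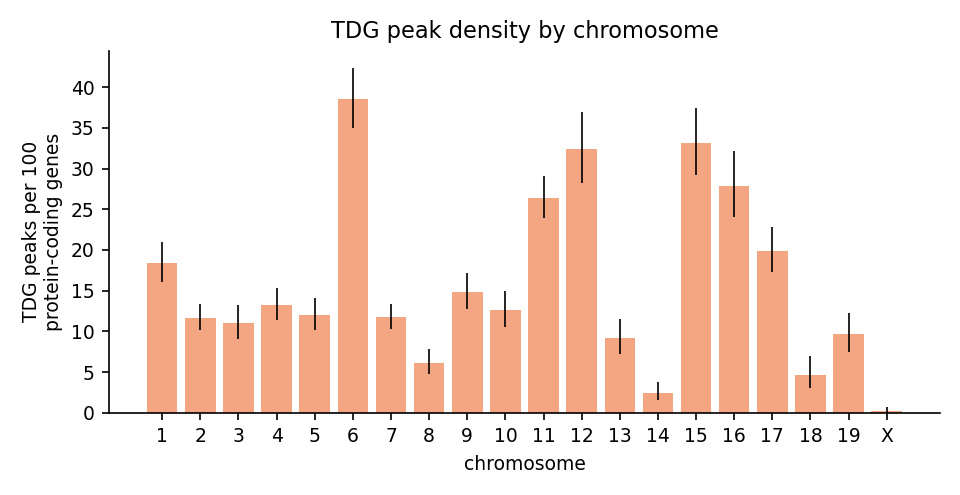
TDG peaks per 100 protein-coding genes (vertical axis) on each autosome and the X chromosome (horizontal axis), with exact Poisson 95% intervals as error bars. Chromosome 6 stands highest at 38.5, and chromosome 14 is the lowest autosome at 2.47.

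The second question was which genes p53 occupied. The p53 peak with the highest fold enrichment (73.4-fold, chromosome 11, 6526781 to 6527572) lay in the noncoding gene Snhg15, 6227 bases from the nearest protein-coding gene, Myo1g. It was followed by a peak 40038 bases from Ier5 (69.7-fold) and one near the predicted gene Gm42048 (54.8-fold). The rest of the 15 highest lay at Phlda3 (47.6-fold), Sp1 (45.6-fold), Itpripl1 (44.0-fold), Pgpep1 (43.3-fold), Bahcc1 (41.7-fold), Trp53inp1 (39.6-fold), Olfr543 (38.0-fold), Zmat3 (36.7-fold), Sergef (36.7-fold), Sfi1 (33.8-fold), Cdkn1a (32.5-fold) and Agbl1 (31.0-fold). For Itpripl1, Bahcc1, Olfr543 and Sfi1 the named gene was the nearest one, since the summit lay outside it at between 1616 and 7717 bases.

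Known p53 target genes were over-represented in this list. Of 55 targets in a fixed list, 16 (29.1%) held a p53 summit or were the gene nearest to one, against 0.44% of other protein-coding genes (odds ratio 92.9, Fisher's exact test, adjusted p = 2.4e-23 over 13 lists). They included the cell cycle inhibitor gene Cdkn1a (p21), the apoptosis genes Bbc3 (30.4-fold) and Bax, and Mdm2 (26.0-fold), which encodes the ubiquitin ligase that degrades p53. Ccng1 (27.8-fold), Aen (25.0-fold), Rps27l (20.5-fold) and Ephx1 (18.4-fold) followed, and Psrc1, Btg2, Ckap2, Rap2b and Plk2 completed the set with Phlda3, Trp53inp1 and Zmat3. No other list passed the test. The ribosomal protein list had 1 member (Rps19, 13.7-fold), the cell cycle list had 1 (Tyms, 12.1-fold), and the other 10 lists had none, among them the melanocyte, homeobox, immune cell and base excision repair lists.

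**Figure D3:**
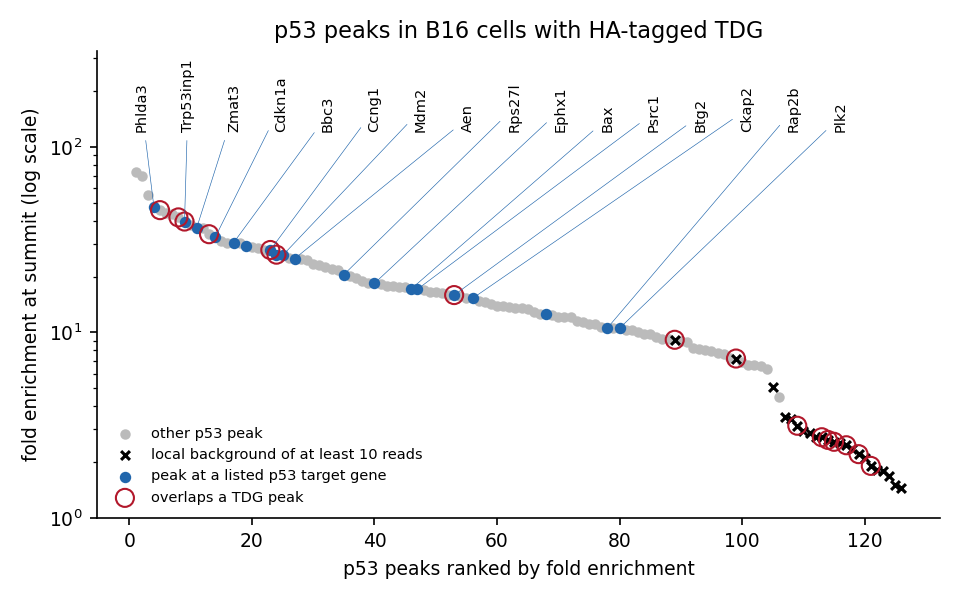
Fold enrichment at the summit (vertical axis, log scale) of the 126 p53 peaks ranked from highest to lowest (horizontal axis). Blue points are peaks at the 16 listed p53 target genes, each gene named at its highest peak, red rings mark the 16 peaks that overlap a TDG peak, and crosses mark the 23 peaks whose local background was at least 10 reads, which gather at the low end.

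TDG was tested against the same gene lists through its gene-end peaks. Of the 55 p53 targets, 18 (32.7%, exact 95% interval 20.7 to 46.7%) had a TDG peak at a gene end, against 12.2% of other protein-coding genes (odds ratio 3.49, Fisher's exact test, adjusted p = 0.00079). The highest were Sertad1 (8.33-fold), Sesn1 (8.07-fold), Btg2 (6.66-fold), Ercc5 (6.63-fold), Apaf1, Polk, Ppm1d and Tigar (each 5.99-fold), Ccng1 (5.73-fold) and Plk2 (5.51-fold). Of the 18, only Btg2, Ccng1, Plk2, Trp53inp1 and Ckap2 were also among the 16 targets assigned a p53 peak. Most targets with a TDG peak at an end therefore had no p53 peak assigned to them. Of 40 cell cycle genes, 14 (35.0%, interval 20.6 to 51.7%) had one (odds ratio 3.86, Fisher's exact test, adjusted p = 0.00115). The highest of these were E2f1 (7.55-fold), Mad2l1 (6.48-fold), Cdc6 and Foxm1 (each 6.25-fold), which encode regulators of replication and mitosis.

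The other 11 lists did not pass the test for TDG. Ribosomal protein genes had a TDG peak at an end in 16 of 73 cases (21.9%, Fisher's exact test, adjusted p = 0.0814), among them Rpl37 (8.59-fold), Rps21 (7.81-fold), Rps19 (7.55-fold) and Rpl27a (7.29-fold). Base excision repair and DNA demethylation genes had one in 7 of 32 cases (exact adjusted p = 0.227), led by Tdg, Tet3 (7.03-fold), Gadd45a (6.67-fold) and Mbd4 (6.18-fold). The melanocyte list had 5 of 26, with Bcan (6.25-fold), Mitf (5.83-fold), Rab38 (5.73-fold) and Gpnmb (4.95-fold) highest, and the CREB target list had 5 of 21, with Siah2 (7.03-fold), Per1 (6.51-fold), Creb1 (6.02-fold) and Nr4a3 (5.99-fold) highest (exact adjusted p = 0.292 for both). The nuclear receptor list had 4 of 28 (exact adjusted p = 0.771), namely Rxrb (6.72-fold), Nr1h2 (6.25-fold), Ep300 (5.99-fold) and Rarg (5.21-fold). Innate immune genes had 2 of 39, Irf3 (6.25-fold) and Irf1 (5.37-fold), and the homeobox list had 1 of 42, Hoxa10 (5.04-fold), with exact adjusted p of 0.292 and 0.182. None of the 21 canonical histone genes (exact adjusted p = 0.227), 15 fibroblast and endothelial markers (0.292), 16 immune cell markers (0.292) or 12 keratinocyte markers (0.415) had a TDG peak at an end. Because peak density differed between chromosomes, genes were also drawn from the chromosomes of each list's own members, an alternative chosen after seeing the data. The p53 targets (2.60 times the draws) and the cell cycle genes (2.75 times) passed there as well (permutation, adjusted p = 0.0026 for each), and so did the homeobox list on the low side (0.147 times, permutation, adjusted p = 0.0468). Both comparisons were with protein-coding genes of any kind. The planned comparison among CpG-rich promoters was not run, so whether these lists differ from genes with like promoters was not tested.

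**Figure D4:**
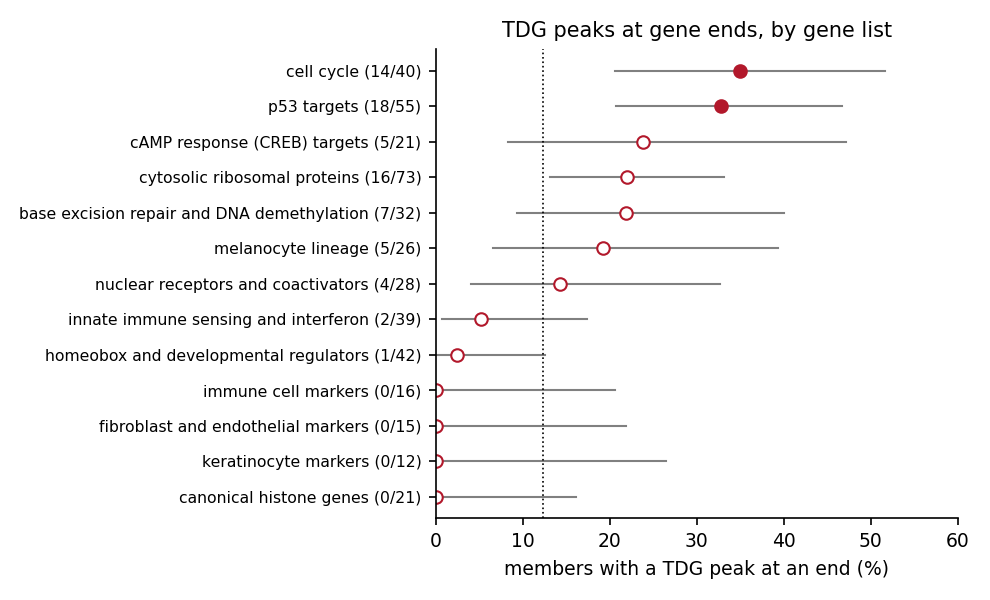
Share of the members of each of 13 gene lists with a TDG peak at a gene end (horizontal axis, percent), with exact 95% intervals as lines and counts in the labels. The dotted line is the share of all protein-coding genes, 12.29%, and filled points are the 2 lists that passed the test, cell cycle at 35.0% and p53 targets at 32.7%.

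The third question was whether TDG and p53 shared sites. A TDG peak overlapped 16 of the 126 p53 peaks by at least 1 base (12.7%, exact 95% interval 7.44 to 19.8%), against a mean of 1.33 when the p53 peaks were shuffled (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give). Of these 16, 9 lay in regions of high background, where the recovered local background was at least 10 reads. These were 5 peaks on unplaced sequence, single peaks in the gene bodies of Zc3h7a (9.12-fold for p53) and Filip1l (7.23-fold), one 21348 bases from Ly6c2 (2.72-fold), and one 105023 bases from Esp38 (2.46-fold). Without such regions, a choice made after seeing the data, 7 of 103 p53 peaks overlapped a TDG peak (6.80%), against a shuffled mean of 0.133, or 0.72 when shuffled peaks stayed within gene ends or outside them (one-sided permutation p = 0.0001 for both, the smallest that 10000 shuffles can give).

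Those 7 shared sites lay at Sp1, Bahcc1, Trp53inp1, Sfi1, Ccng1, Cdkn1a and Btg2. The strongest for both proteins was Sp1 (45.6-fold for p53, 9.11-fold for TDG), whose p53 peak (chromosome 15, 102405709 to 102406192) lay wholly within the TDG peak. At Trp53inp1 (chromosome 4, p53 peak 11156029 to 11156406) the enrichments were 39.6-fold for p53 and 4.95-fold for TDG, with summits 58 bases apart. At Ccng1 (chromosome 11, 40755267 to 40755630) they were 27.8-fold and 5.73-fold, and at Btg2 (chromosome 1, 134079271 to 134079577) 15.9-fold and 6.66-fold. Bahcc1 (41.7-fold and 4.95-fold) and Sfi1 (33.8-fold and 4.94-fold) had their shared peaks 2832 and 7717 bases outside the gene. At the shared site near Sfi1 the p53 summit lay in the pseudogene Pisd-ps1 and the TDG summit outside it, with a local background of 5 reads in the TDG list, and 2 further p53 peaks inside Sfi1 had local backgrounds of 44 and 81 reads.

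At Cdkn1a (chromosome 17, 29090979 to 29100722) the shared site was not the p53 peak at the gene end. p53 had 3 peaks there, one 36 bases from the lower gene end (29090720 to 29091201, 32.5-fold), one inside the gene (29094384 to 29094688, 12.6-fold) and one 11930 bases below it (29078888 to 29079200, 26.2-fold), within the noncoding gene Trp53cor1 (lincRNA-p21). TDG overlapped the last of these (29078956 to 29079224, 6.51-fold), with summits 63 bases apart. Its other peaks at Cdkn1a lay at 29080844 to 29081294 (4.95-fold), at 29081963 to 29082488 (6.25-fold) and, inside the gene, at 29093515 to 29093875 (7.23-fold), and none of these overlapped a p53 peak.

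**Figure D5:**
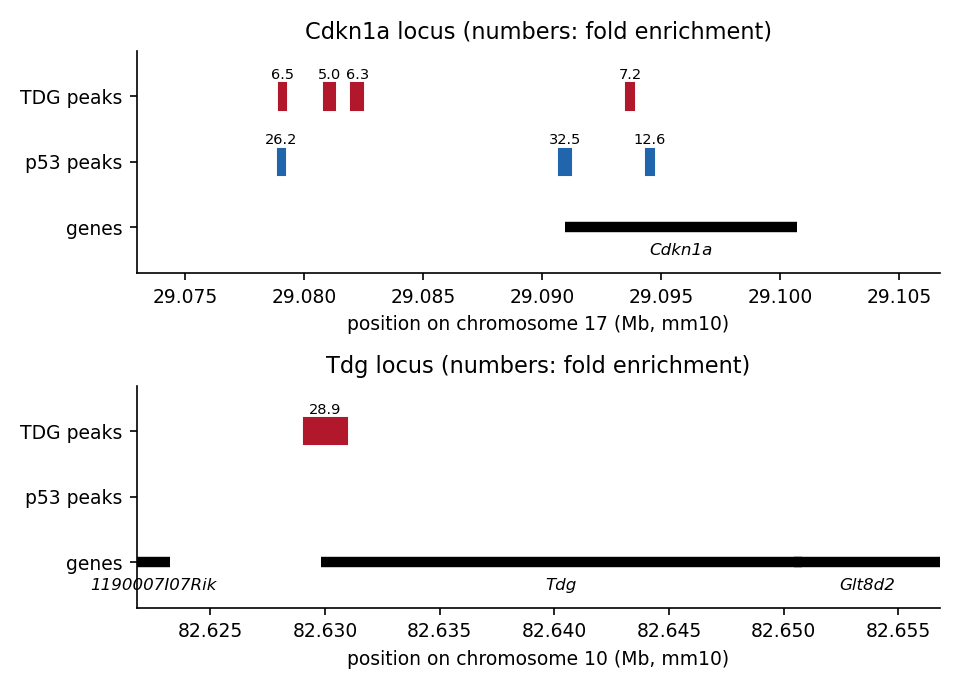
Maps of the Cdkn1a and Tdg loci (horizontal axes, position in Mb, mm10) with TDG peaks in red, p53 peaks in blue, protein-coding genes in black and the fold enrichment above each peak. TDG and p53 overlap at the site below Cdkn1a (6.5 and 26.2), and the Tdg gene end carries the 28.9-fold TDG peak with no p53 peak.

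By fold enrichment, TDG peaks shared with p53 were lower than the rest, but not outside regions of high background. The 15 TDG peaks that overlapped a p53 peak had a median fold enrichment of 4.94 against 5.74 for the other 3395, a difference of -0.803 (two-sided permutation p = 0.0444). Over the same 15 and 3395 peaks, the difference in median −log10 q was 2.39 (permutation p = 0.0699). Without the regions of high background the medians were 5.73 for 7 peaks and 5.74 for 3388, a difference of -0.00993 (permutation p = 0.99).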

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

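Leaving out regions of high background, drawing list genes from the same chromosomes and the test of p53 strength at shared peaks were chosen only after the data were seen. The shares at gene ends kept their direction and call under every alternative run (67.2 to 76.0% for TDG, 20.6 to 32.5% for p53), as did the stronger TDG enrichment at gene ends. Their ratios to the shuffled shares moved more, from 20.7 to 8.71 for TDG and from 6.39 to 3.73 for p53 with the 3 kb window, and to 11.1 and 5.12 with the ends of all annotated genes, because shuffled peaks reached these wider targets more often. The overlap of 16 p53 peaks lay between 11 and 15 under 4 other settings, rose to 26 when peaks within 1 kb were counted, and fell to 7 without regions of high background under either shuffle, since 9 of the 16 lay there. Every one of these stayed above its shuffled mean with permutation p = 0.0001, the smallest 10000 shuffles can give. The lower TDG enrichment at shared peaks was not stable: its difference of -0.803 became -0.789 without unplaced sequence (permutation p = 0.1), -0.00993 without regions of high background (permutation p = 0.99) and 2.39 on the −log10 q scale (permutation p = 0.0699). The p53 enrichment at shared peaks turned from -5.45 (permutation p = 0.0693) to 18.6 without regions of high background (7 against 96 peaks, permutation p = 0.00306). The cause was not tested beyond the removal of those peaks. Among single gene lists, 101 values kept direction and call, and 1, the homeobox list against draws from the same chromosomes, passed only there. The nuclear receptor list passed in no setting and had 4 of 28 members with a peak in each, so only the comparison genes moved its values. Its odds ratio went from 1.19 to 0.997 with the 3 kb window, where the share of other genes rose from 12.3% to 14.3%. Against draws from the same chromosomes its count was 0.962 times the draws, which is not an odds ratio. CpG content, motifs, CpG-rich promoters and repeat masking were not run for want of a genome sequence. No paired analysis was possible because each group had 1 library. Library totals are not given, and the effect of library depth on which sites were called was not tested.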

Other observations

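All tests in this part were chosen only after the result was seen, except the one across windows with at least 5 TDG peaks, whose prediction was written before its result. Of 112 genes assigned to p53 peaks, 21 (18.8%) had a TDG gene-end peak against 12.3% of the others (odds ratio 1.65, Fisher's exact test, p = 0.0429), and without regions of high background the count was 20 of 101 (odds ratio 1.77, exact p = 0.0316). These comparisons were not matched for chromosome. Chromosomes 14, 18, X and Y had no p53 peak and few TDG peaks, so their genes entered only the comparison group and lowered its share. Whether chromosome accounts for the excess was not tested. Of the 21, 6 were genes of the overlapping peaks already described, so this count is not independent of the overlap. Without the genes assigned to those peaks 15 of 100 had one, near the 12.3% of the others, though this removes genes by the outcome. These 15 included the lamin gene Lmna (18.9-fold for p53 and 5.19-fold for TDG), whose p53 peak lay in the gene body. For most of the 15, however, the p53 peak lay outside the gene, which was only the nearest one. Examples were Maml1, a Notch coactivator gene (19.7-fold and 6.06-fold), at 3253 bases, and Myc (13.4-fold and 6.49-fold), at 48855 bases in the noncoding gene Pvt1. A further example was Nfe2l2, which encodes the oxidative stress regulator NRF2 (28.6-fold and 5.83-fold), at 63720 bases. The p53 peaks at the listed p53 targets were also stronger than the rest, with a median of 25.0-fold for 19 peaks against 12.1-fold for the rest of the 126 (two-sided permutation p = 0.00049), and against 14.4-fold without the regions of high background, where none of the 19 lay (permutation p = 0.00295).

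The uneven density of TDG peaks between chromosomes was the pattern that most called for a technical reading. Gene number alone is argued against, since chromosome 6 had 15.6 times as many TDG peaks per 100 genes as chromosome 14 and their intervals did not overlap. DNA copy number or read depth of the chromosome is a candidate explanation: across 20 chromosomes the density rose with the share of TDG peaks whose local background exceeded the genome-wide one (Spearman rho = 0.821, permutation p = 1e-05, the smallest 100000 permutations can give, adjusted p = 3e-05 over 3 correlations; Pearson r = 0.81, permutation p = 0.0001, the smallest 10000 can give), and without chromosomes 6 and X, the 2 farthest, rho was 0.754 (permutation p = 0.00047) and r 0.69. Across 170 windows of 10 Mb with at least 10 genes and 5 TDG peaks, which are not independent replicates, the relation within chromosomes was weaker in the same direction (rho = 0.308, permutation p = 4e-05, adjusted p = 6e-05), as it was across the 239 with at least 1 TDG peak (rho = 0.33, permutation p = 1e-05). The p53 peaks outside regions of high background gave rho = 0.444 with TDG density (permutation p = 0.0505), which leaves open whether they share it, and no biological explanation was tested.

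The shared peaks were a mixture. Reads of repeats collapsed in the reference, pulled down with any antibody, may account for 9 of them: with p53 peaks within 50 kb of each other counted as 1 region, 5 of 11 regions of high background (45.5%) overlapped a TDG peak against 7 of the other 99 (7.07%; odds ratio 11.0, Fisher's exact test, p = 0.00211), but the limit of 10 reads was set after the lists were seen and the IgG sample, which bears on this directly, was not analysed here. On chromosome 17, 2 p53 peaks beside the shared one near Esp38 lay in Rn18s-rs5, annotated as a pseudogene. No shared peak of high background on a placed chromosome had such an annotation at its own summit, the one near Esp38 included. The genes used did not cover unplaced sequence, so the shared peaks there could not be looked up. The 7 others fell below that limit, but this does not clear the site near Sfi1, where the TDG background was 5 reads and the p53 summit lay in a pseudogene. The p53 background at that site was only the genome-wide 2.028 reads. The p53 peaks with backgrounds of 44 and 81 reads lay inside Sfi1, more than 50 kb from it. For the other 6, binding of TDG and p53 to the same open chromatin remains untested.

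The 28.9-fold TDG peak at Tdg was the only one above 15-fold. Extra copies of Tdg sequence from the tagging could raise reads there, but the local background at the peak was 1.22 times the genome-wide one, and no p53 peak lay within 10 kb although the p53 library came from cells with the same tag. To account for the peak, the copies would have to be missing from the control of the TDG list and present in that of the p53 list. The control libraries are not given in the sources used here, and the control reads recovered from the backgrounds, 9.80 per kb for the TDG list and 10.3 for the p53 list, would be equal for 1 control called alike. Extra copies therefore cannot be told apart from binding of TDG at its own gene.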
